A study of Mus musculus with 8 samples.

How the data were processed

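Small RNA of sperm was profiled in 8 libraries of 8-month-old Balb/c mice: 2 control, 2 MC-LR, 2 negative-control shRNA and 2 Hsp90aa1 shRNA. Groups and replicate letters were taken from the sample titles. The series' design text speaks of different MC-LR doses, but the labels give no dose, so none is used here. Nothing in the labels says that the 2 libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

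The authors deposited 2 tables, control with MC-LR and negative-control with Hsp90aa1 shRNA, that give a locus, a strand, a piRNA name and an RPM value in each of 4 libraries. Columns were matched to samples by their group and replicate letters. Per the submitters' processing notes, Bowtie2 2.2.3, HISAT2 2.1.0 and HTSeq 0.6.0 were used with the mm10 genome build; which tool did which step, the read trimming, the total behind the RPM scale and the rule by which loci were listed are not given in the sources used here. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with an RNA library kit. All deposited RPM values were whole multiples of the value of 1 read of their library (100% within 0.01 of a whole number), which gave back the reads and the library totals, 4960467 to 14634370 reads. The sum of the listed names is only part of those totals. A floor of 3 reads corresponds to 0.205 and 0.605 RPM in control A and B, 0.505 and 0.457 in MC-LR A and B, 0.309 and 0.224 in negative-control shRNA A and B and 0.225 and 0.277 in Hsp90aa1 shRNA A and B. The median name had 98.5 and 33 reads in the control libraries, 13 and 15 under MC-LR, 46 and 58 with the negative-control shRNA and 10 and 5 with the Hsp90aa1 shRNA. These limits cover counting error only, since the reads carry no molecular identifiers.

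The MC-LR table lists 22956 loci of 13450 names and the other table has 29960 loci of 17375 names, all of 17 to 35 nt. Of the names at more than 1 locus, 5579 of 5743 and 7250 of 7499 hold the same values at every locus, so reads that fit several loci were counted at each. Each name was therefore used once, at the locus with the highest mean. Names overlap each other along the genome and may share reads, and near-identical sequences listed under other names cannot be separated, so names are not independent measurements. Starts were read as 0-based and are printed 1-based. This was tested on the let-7 hairpins of the plus strand, where 75 of 86 loci then begin with the let-7 sequence TGAGGTAG, against 3 if starts are read as 1-based.

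Loci were assigned to a class with the GENCODE M21 and RefSeq annotations of GRCm38 (mm10), by an overlap of at least a share of 0.5 of the locus, in the order ribosomal RNA, transfer RNA, snoRNA, other small structural RNA, microRNA gene, protein-coding exon, long noncoding exon, inside a gene, outside genes. RefSeq entries were matched without strand. Ribosomal RNA includes the 45S repeat copy at 17:39843013–39848827. A name took the first of these classes among its loci, so its class gene may lie at another locus than the one printed. Clusters were loci within 10 kb of each other with at least 10 tested names.

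The unit decided the test, by the rule written before the data were examined for normalized values: limma 3.58.1 (trend and robust empirical Bayes) in R 4.3.3 on log2(RPM + 1), for names with a mean of at least 1 RPM in at least 1 group, each table alone, with Benjamini-Hochberg adjustment at 0.05. Class, length and chromosome groups were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. As an addition after the data were seen, the recovered reads were tested with edgeR 4.0.16 (quasi-likelihood), which on library totals called 9658 names lower and 314 higher under MC-LR and 16317 lower and 37 higher with the shRNA, and with DESeq2 1.42.0. The test of the difference between both effects was planned only for raw counts. It was added after the data were seen, in limma over the names of both tables, which were scaled apart. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

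Names to print were chosen by a rule fixed before the data were examined. In each comparison these were, among names past the threshold with groups that do not overlap and at least median abundance, the 8 with the largest rise and the 8 with the largest fall; the 4 most abundant names past the threshold; up to 4 names with the smallest p in each group, here the RNA classes and the ranges of 24 to 28 and 29 to 33 nt; and the 6 most abundant names whatever their test. Of these, 53 names in the shRNA comparison and 52 in the MC-LR comparison, the most telling of each class are printed. Chromosomes and clusters are given as groups only. The 7 extended regions were chosen after their values were seen, as clusters of the MC-LR table with at least a share of 0.5 of tested names higher.

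The fit was tested on simulated reads with 200 changed names. For the MC-LR comparison limma recovered 3 of 59 names changed 2-fold, 28 of 64 changed 4-fold and 60 of 65 changed 8-fold, and called 5 of 12621 unchanged names. For the shRNA comparison it recovered 0 of 60, 1 of 59 and 14 of 59 names at those folds and called 1 of 15206 unchanged names. With so few names changed the adjustment is stricter than in these tables, where most names pass.

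Alternatives were a pseudocount of 0.1, no filter, an FDR of 0.1, a minimum log2 fold change of 1, a replicate block, each library left out, other scalings and tools on the recovered reads, other abundance filters, every locus as a feature, names at 1 locus and names off structural RNA and microRNA genes. The gene lists fixed beforehand (piRNA pathway, chaperones, germ and somatic cell markers, stress, phosphatase, mitochondrial and silencing genes) were not used, because the features are small RNAs and not genes, and the markers of other cell types have no values here. The base composition of the piRNAs, first base U included, was not analysed here, since no genome sequence was used.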

Results

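Small RNA fragments listed under piRNA names were measured in sperm of 8-month-old Balb/c mice. piRNAs are small RNAs that bind PIWI proteins in germ cells and silence transposable elements. The 4 groups held 2 libraries each, lettered A and B: a control, MC-LR, a negative-control shRNA and an shRNA against Hsp90aa1. MC-LR is microcystin-LR, a cyanobacterial toxin that inhibits the serine/threonine phosphatases PP1 and PP2A, and Hsp90aa1 encodes the cytosolic chaperone HSP90 alpha. The values were RPM, reads scaled to a common library total, in 2 deposited tables, 1 for each pair of groups, with 13450 piRNA names in the MC-LR table, 17375 in the shRNA table and 10615 in both. The total behind the RPM scale was 14634370 reads in control A, 4960467 in control B, 5941139 in MC-LR A and 6560723 in MC-LR B. It was 9710383 and 13380630 reads in the negative-control shRNA libraries A and B and 13360928 and 10832261 in the Hsp90aa1 shRNA libraries. Summed over names, the listed values came to 38.1% and 35.3% of those totals in the control libraries and 12.5% and 11.7% under MC-LR. They came to 27.8% and 32.5% with the negative-control shRNA and 4.98% and 3.18% with the Hsp90aa1 shRNA. Names overlap and may share reads, which was not tested, so reads may count more than once in these sums. Many listed names lie on other small RNA genes: 8300 names (61.7%) of the MC-LR table and 9852 (56.7%) of the shRNA table overlapped a ribosomal RNA, transfer RNA, snoRNA, other small structural RNA or microRNA gene.

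The first comparison asked how piRNAs of sperm differ after MC-LR. Per library total, most names of every RNA class were lower by mean RPM. In every class but long noncoding exons (70 of 144) most tested names also passed the threshold as lower. A set of long piRNAs from extended genomic stretches was higher. Scaled within the list, the median of snoRNA names stayed below 0 and that of ribosomal and transfer RNA turned above 0. Of 13271 names tested, 9703 were lower and 314 higher under MC-LR at a false discovery rate of 0.05, and 3254 did not pass. The deepest fall was on snoRNA, the guides for chemical modification of ribosomal RNA, whose summed level went from 90678 ± 9795 RPM in control to 17084 ± 1445 RPM under MC-LR (SD, n = 2 each), 5.31-fold lower. Of the rising names 130 lay in 7 extended regions, and the region with the most of them, 17:27292140–27358271, went from 46.5 ± 12.1 to 556 ± 84.7 RPM (SD, n = 2 each), 12.0-fold higher. Fold changes of single names are on the log2(RPM + 1) scale of limma, which understates the change of low names.

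Among names on snoRNA genes, 2065 of 2200 fell and 135 did not pass; with scaling within the list (edgeR with TMM factors) 264 of 2045 were lower. The leading examples were piR-mmu-4679168 at 11:69668854–69668881 in the snoRNA gene Gm25835, from 115 ± 10.4 to 3.49 ± 0.887 RPM (SD, n = 2; log2 fold change −4.71 ± 0.35 SE, limma adjusted p = 2.41e-04), and piR-mmu-1461305. The second lies at 4:132309575–132309600 in Snora16a and went from 48.0 ± 0.821 to 1.28 ± 0.0899 RPM (SD, n = 2; log2 fold change −4.42). Snord80 (piR-mmu-62176622, 1:161037651–161037675, −4.36), Snora24 (piR-mmu-2360037, 3:123507937–123507963, −4.18) and Snord16a (piR-mmu-20639312, 9:64175494–64175520, −4.01) held further examples. A pair of overlapping names in the snoRNA locus at 19:8724573–8724600, piR-mmu-2047156 and piR-mmu-18443, were among the most abundant of all. They fell by 2.18 and 2.12 on the log2 scale, from 5288 ± 1265 and 4520 ± 664 RPM (SD, n = 2). With TMM factors both lost their call, at −0.52 and −0.44 (edgeR adjusted p = 0.446 and 0.495). As a set, snoRNA names fell further than the rest of the list, with a median log2 fold change of −2.03 against −1.09 (camera adjusted p = 9.37e-18; adjusted p = 0.0606 with an estimated correlation).

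Ribosomal RNA names fell in 3971 of 5240 cases, with 1269 not past the threshold, although their median turned to 0.08 with TMM factors. Their sum went from 102233 ± 9085 to 34940 ± 2035 RPM (SD, n = 2), 2.93-fold lower. Overlapping names that start at 17:39847742, in the copy of the 45S repeat on chromosome 17, led this class: piR-mmu-52883220 (31 nt, −3.98), piR-mmu-2008060 (28 nt, −3.86) and piR-mmu-1382758 (29 nt, −3.80). Transfer RNA names fell in 82 of 121 cases, with 39 not past the threshold and a median of 0.16 with TMM factors. The leading name, piR-mmu-7898656 at 1:171066634–171066657 in a glycine tRNA gene, fell by 2.64 (−1.02 with TMM factors, edgeR adjusted p = 0.150). Other small structural RNA had 153 lower, 1 higher and 48 not past the threshold of 202 names. Both directions occurred among names that match Rnu12, the U12 RNA of the minor spliceosome. There piR-mmu-53265993 at 15:83149762–83149794 fell from 89.8 ± 53.5 to 9.43 ± 2.39 RPM (SD, n = 2), without a call under TMM factors (edgeR adjusted p = 0.113). The name piR-mmu-48885749 at 15:83149713–83149730 rose from 11.6 ± 4.69 to 142 ± 17.7 RPM (SD, n = 2; log2 fold change 3.56, limma adjusted p = 2.41e-04). It has 18 nt and is listed at 2 loci, so its reads cannot be assigned to Rnu12.

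Names on microRNA genes fell in 284 of 447 cases, 1 rose and 162 did not pass, with a median of 0.44 under TMM factors. Their sum went from 40682 ± 11989 to 21253 ± 1926 RPM (SD, n = 2), 1.91-fold lower. Mir210, a microRNA of the hypoxia response, had the leading fall (piR-mmu-10872739, 7:141221406–141221428, −2.52), followed by Mir204 (piR-mmu-17599573, 19:22750610–22750633, −2.09) and Mir125a (piR-mmu-13826650, 17:17830817–17830840, −2.06). With TMM factors none of them passed, at −1.61, −0.54 and −0.43 (edgeR adjusted p = 0.0794, 0.478 and 0.545). The most abundant name of the table, piR-mmu-48707800 at 6:51269829–51269850 in Mir148a, did not pass. It stood at 14235 ± 4923 RPM in control and 8123 ± 1951 RPM under MC-LR (SD, n = 2; log2 fold change −0.79, limma adjusted p = 0.0651). Nor did piR-mmu-10879204 in Mirlet7c-2, a member of the let-7 family (15:85706616–85706637; 3177 ± 1116 against 2167 ± 337 RPM, SD, n = 2; log2 fold change −0.51, limma adjusted p = 0.183). That name is listed at 3 loci, so its reads cannot be assigned to Mirlet7c-2. Outside annotated genes, the abundant names piR-mmu-48788131 (6:3201476–3201496) and piR-mmu-49575097 (10:82955393–82955412) both fell by 1.55. These 4 abundant names reversed with scaling within the list (edgeR with TMM factors), to between 0.09 and 1.16. Without control B, the Mir148a and Mirlet7c-2 names passed, at −1.15 and −0.88 (limma adjusted p = 2.10e-04 and 0.00607).

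Protein-coding exons held 505 lower, 9 higher and 178 unpassed names of 692, with a median of 0.11 under TMM factors. Leading falls were in Snrpb, a core protein gene of the spliceosome (piR-mmu-20833075, 2:130172908–130172934, −3.26), and in Lars2, the mitochondrial leucyl-tRNA synthetase (piR-mmu-2360702, −3.53). The Lars2 name is listed at 5 loci, with its highest level at 11:96081154–96081177, so its reads cannot be assigned to Lars2. Long noncoding exons were the most mixed class, with 70 lower, 32 higher and 42 not past the threshold of 144, and a median of 0.50 under TMM factors. As a set they lay above the rest of the list, with a median log2 fold change of −0.87 against −1.18 (camera adjusted p = 3.66e-19; adjusted p = 0.0803 with an estimated correlation). Names inside genes but outside sense exons had 1396 lower and 72 higher of 2282, and names outside annotated genes 1177 lower and 199 higher of 1943, with medians of 0.33 and 0.35 under TMM factors. Both sets also lay above the rest by camera (adjusted p = 0.00627 and 1.96e-10; adjusted p = 0.392 and 0.0606 with an estimated correlation). Ribosomal RNA, transfer RNA and other small structural RNA did not differ from the rest by camera past the threshold (adjusted p = 0.325, 0.850 and 0.456), nor did microRNA genes, protein-coding exons and names of 29 to 33 nt (adjusted p = 0.135, 0.957 and 0.119). Names of 24 to 28 nt lay slightly below the rest, by 0.06 in median log2 fold change (camera adjusted p = 0.0388; adjusted p = 0.869 with an estimated correlation). By chromosome, names on chromosome 19 lay below the rest and those on chromosomes 5 and 7 above by camera (adjusted p = 0.00276, 0.0362 and 0.00508; adjusted p = 0.272 with an estimated correlation for all 3). The median of chromosome 7 nevertheless lay on the other side of the rest (difference −0.13). Adjusted over the list alone, 2096 snoRNA, 3975 ribosomal RNA, 81 transfer RNA and 250 microRNA gene names were lower.

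The 314 rising names had a median length of 29 nt, 201 of them were 29 to 33 nt long, and 287 had a single listed locus. The 7 regions that held 130 of them were 18.7 to 66.1 kb long, and of the 133 names listed there 1 fell. Such stretches, each giving many piRNAs of one long precursor, are the usual sources of pachytene piRNAs in the mouse. The chromosome 17 region had 43 rising names of 44, among them piR-mmu-2597977 at 17:27356495–27356523 in an exon of the noncoding gene Gm49794. This name rose from 12.4 ± 5.27 to 148 ± 45.4 RPM (SD, n = 2; log2 fold change 3.50 ± 0.40 SE, limma adjusted p = 2.41e-04), and piR-mmu-117350 at 17:27348375–27348404, outside genes, by 3.34. All 20 names of 2:92542029–92582152 rose, and their sum was 15.3-fold higher (9.17 ± 1.86 to 141 ± 20.9 RPM; SD, n = 2). In 18:67039743–67073689 all 15 rose, with a sum 17.2-fold higher, in 6:127785862–127805324 all 13, 13.3-fold, and in 5:113337817–113356536 all 10, 13.7-fold. In 9:67698367–67749737 there were 18 rising names of 19, 10.3-fold by the sum, and in 5:149801387–149824796, which holds exons of the noncoding gene Gm21221, 11 of 12, 10.5-fold. By camera all 7 lay above the rest (adjusted p between 9.60e-175 and 5.02e-51; adjusted p between 0.299 and 0.321 with an estimated correlation). The regions were picked because at least a share of 0.5 of their tested names rose, so these values describe them and do not test them. Rising names elsewhere included piR-mmu-8117009, listed at 3 loci with its highest level at 1:167340462–167340481 and another in Zc3h7a (3.76), piR-mmu-2604210 at 14:24093335–24093363 (3.48), piR-mmu-49306705 at 2:130636504–130636523 in Lzts3 (3.34) and piR-mmu-2662924 at 6:127832306–127832334 (3.22).

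**Figure D1:**
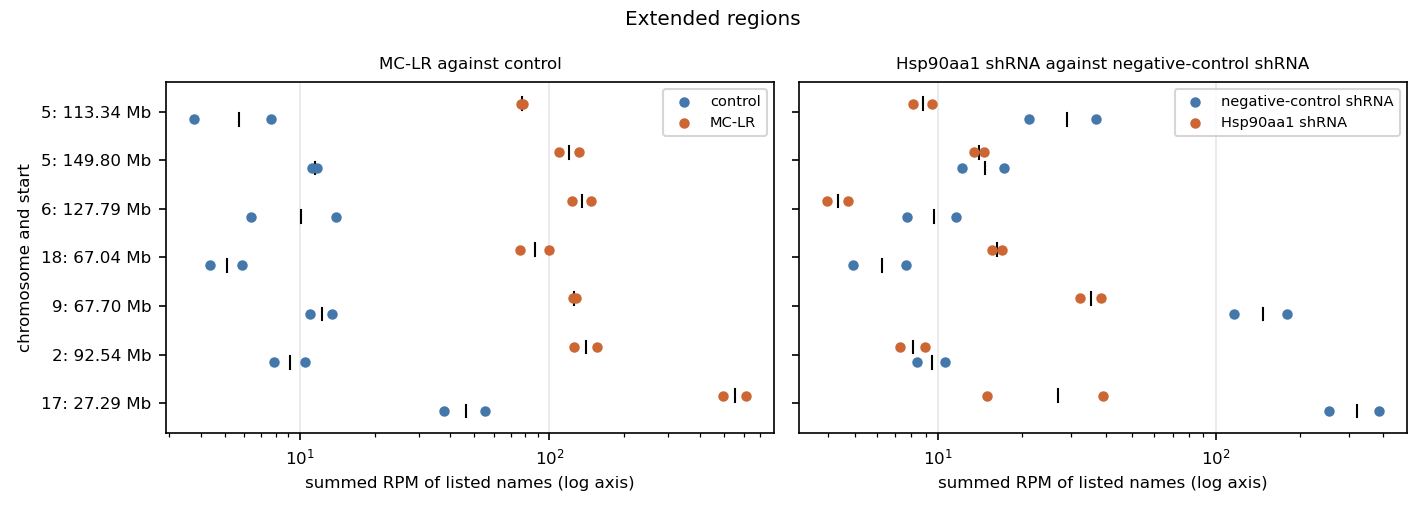
Summed RPM of listed names (log axis) in each of 7 extended regions, named by chromosome and start, with 1 point per library and a vertical bar at the group mean (n = 2). All 7 sums were higher in both MC-LR libraries than in both control libraries (left), by 10.3-fold to 17.2-fold; with the shRNAs (right) the chromosome 17 sum was 11.9-fold lower and that on chromosome 18 2.59-fold higher.

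All 13450 names were above 0 in each of the 4 libraries and only 2 had a log2 ratio of group means within 0.5 of 0, so the table held almost no unmoved names and its calls are not independent evidence of direction. The groups did not overlap for 12608 names, where chance gives a share of 0.33 with 2 libraries against 2 and an exact permutation p cannot go below 0.33. Scaling within the list (edgeR with TMM factors) moved the median log2 fold change of all names from −1.63, in edgeR on library totals, to 0.06 and the calls to 320 lower and 316 higher. Only the medians of snoRNA (−1.03) and other small structural RNA (−0.17) then stayed below 0. The count of lower names was 5259 without MC-LR A and 5373 without MC-LR B.

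**Figure D2:**
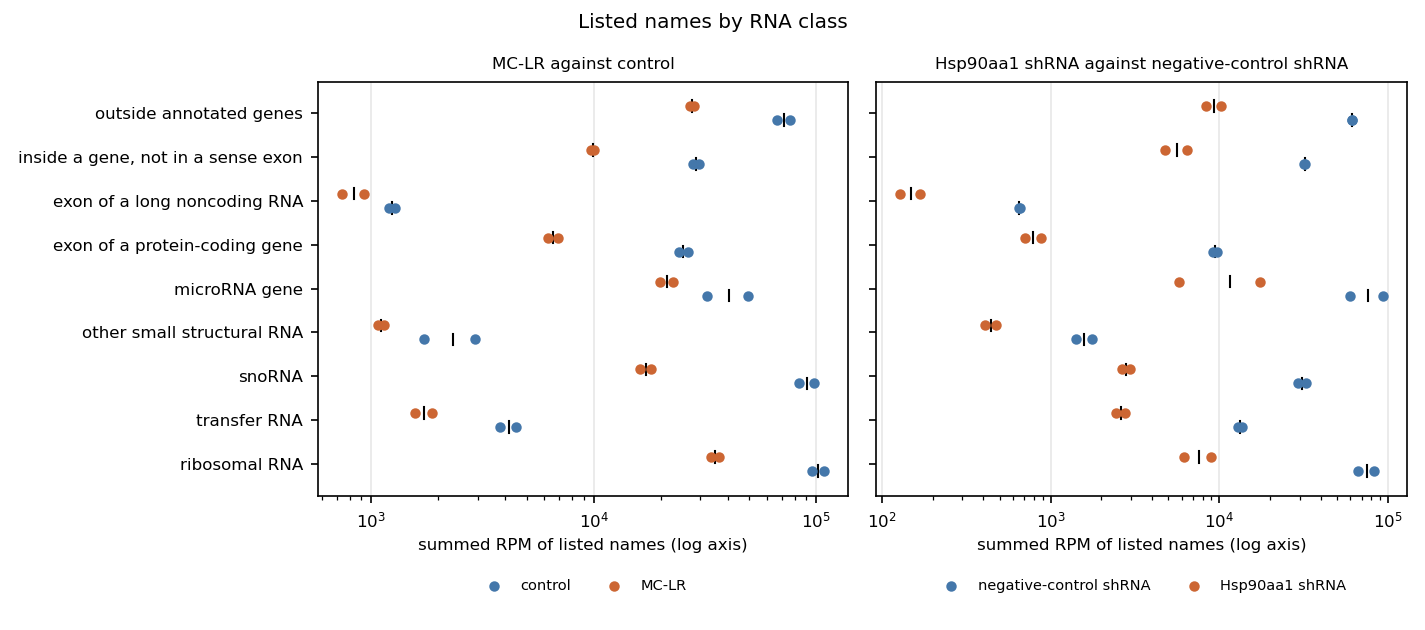
Summed RPM of listed names (log axis) by RNA class in the control and MC-LR libraries (left) and the shRNA libraries (right), with 1 point per library and a vertical bar at the group mean (n = 2). Every class sum was lower in both treated libraries than in both reference libraries, from 1.48-fold (long noncoding exons) to 5.31-fold (snoRNA) under MC-LR and from 3.58-fold to 11.9-fold with the Hsp90aa1 shRNA; with scaling within the list (edgeR with TMM factors), the class medians of log2 fold change were above 0 except for snoRNA and other small structural RNA under MC-LR and for ribosomal RNA, transfer RNA and snoRNA with the shRNA.

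The second comparison asked how piRNAs of sperm differ with the shRNA against Hsp90aa1. Hsp90aa1 itself is a messenger RNA and has no value among these small RNAs, so its own level was not analysed here. Nearly the whole list was lower per library total, a shift that scaling within the list takes away. Of 16859 names tested, 16773 fell, 37 rose and 49 did not pass. The steepest class sums were those of protein-coding exons, 11.9-fold lower (9422 ± 390 to 789 ± 123 RPM), of snoRNA, 11.1-fold lower (31049 ± 2291 to 2803 ± 200 RPM), and of ribosomal RNA, 9.92-fold lower (74987 ± 11596 to 7561 ± 1979 RPM; SD, n = 2 each). By median log2 ratio of group means the order was another, with snoRNA at −3.26, transfer RNA at −3.21, ribosomal RNA at −3.06 and protein-coding exons at −2.81. The shallowest sum was that of other small structural RNA, 3.58-fold lower (1582 ± 240 to 442 ± 48.7 RPM; SD, n = 2). The 37 names that rose were long, with a median of 30 nt, and 25 of them lay outside annotated genes.

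Ribosomal RNA names fell in 6066 of 6076 cases and 10 did not pass. The name with the largest fall of the comparison, piR-mmu-49083875, has 18 nt and its highest listed level at 16:18533313–18533330. It matches the 45S repeat at its other locus and went from 12421 ± 9367 to 33.1 ± 28.9 RPM (SD, n = 2; log2 fold change −8.59 ± 0.91 SE, limma adjusted p = 5.70e-04). piR-mmu-57637038, also on the 45S repeat at another of its 3 loci, fell by 6.74. All 1751 snoRNA names fell, led by Snord60 (piR-mmu-15709216, 17:24528476–24528500, from 217 ± 26.1 to 1.13 ± 0.418 RPM; SD, n = 2; log2 fold change −6.69, limma adjusted p = 5.70e-04). Snord104 (piR-mmu-29449009, 11:106500991–106501017, −6.53) and Snord66 (piR-mmu-49237870, 16:20684239–20684258, −6.47) followed. Transfer RNA names fell in 498 of 502 cases. The abundant glycine tRNA name piR-mmu-10849969 at 1:171066631–171066660 went from 2400 ± 901 to 536 ± 146 RPM (SD, n = 2; log2 fold change −2.13, limma adjusted p = 0.0194), and piR-mmu-12633674 at 7:26460859–26460888 in Nlrp4a had nearly the same levels, 2324 ± 881 and 515 ± 140 RPM (SD, n = 2). Both lost their call without negative-control shRNA A (limma adjusted p = 0.312 and 0.309) and without B (0.112 and 0.109). Of the 176 names on other small structural RNA, 174 fell and 1 rose, and the leading falls were on Rny3 (piR-mmu-10833142, 6:47781624–47781650, −2.21) and Rny1 (piR-mmu-49042250, 6:47788158–47788180, −2.91), genes of the Y RNAs that bind the Ro protein.

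MicroRNA gene names fell in 1067 of 1072 cases and 5 did not pass. Mir148a was again the most abundant of them (piR-mmu-48707800, from 6232 ± 1667 to 607 ± 516 RPM; SD, n = 2; log2 fold change −3.66 ± 0.89 SE, limma adjusted p = 0.00338). Mir143 (piR-mmu-48713555, 18:61649198–61649219, −3.27) and Mirlet7g (piR-mmu-10842452, 9:106178846–106178867, −2.07) fell as well, as did Mir204 (piR-mmu-17599573, −3.66), Mirlet7b (piR-mmu-10881604, 15:85707325–85707348, −3.90) and Mir5099 (piR-mmu-49108075, 12:36816248–36816268, −4.00). The Mirlet7g name did not pass without either negative-control shRNA library (limma adjusted p = 0.178 and 0.278) or without Hsp90aa1 shRNA B (0.108), nor did the Mir143 name without negative-control shRNA B (0.0559). The summed level of the class, 76766 ± 23940 against 11588 ± 8178 RPM (SD, n = 2), had the widest spread between the Hsp90aa1 shRNA libraries of the 9 classes, 17370 RPM in A and 5805 RPM in B.

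Of 662 names on protein-coding exons, 661 fell, and of 3350 inside genes 3340. The leading names of both classes had nearly equal levels, so they may share reads and their gene of origin cannot be told. piR-mmu-3728764, assigned to Lars2 at another of its 4 loci than the highest, 11:96081154–96081179, went from 424 ± 77.6 to 2.06 ± 0.690 RPM (SD, n = 2; log2 fold change −7.12, limma adjusted p = 5.70e-04). piR-mmu-4880618 at 12:78351149–78351174 in Gphn, the gene of the synaptic scaffold gephyrin, went from 421 ± 77.5 to 2.01 ± 0.755 RPM (SD, n = 2; −7.14). piR-mmu-55533771 in 5430416N02Rik fell by 6.95 (5:100426926–100426955). Of 133 long noncoding exon names 127 fell and 5 rose, and of 3137 names outside annotated genes 3089 fell, 25 rose and 23 did not pass.

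By camera, other small structural RNA, long noncoding exons, names inside genes and names of 29 to 33 nt fell less than the rest of the list (adjusted p = 1.38e-05, 1.73e-04, 0.0231 and 1.73e-04), and snoRNA, ribosomal RNA and names of 24 to 28 nt fell further (adjusted p = 0.0143, 0.0443 and 0.00429). Each of these 7 had an adjusted p = 0.804 with an estimated correlation. The median of names of 24 to 28 nt lay above that of the rest by 0.08, opposite to the test. For microRNA genes, which did not pass (camera from limma, adjusted p = 0.348), the median lay below the rest (−0.32) while the test pointed up. Transfer RNA, protein-coding exons and names outside genes did not pass either (adjusted p = 0.269, 0.364 and 0.101). Names on chromosome 15 lay above the rest (camera adjusted p = 0.0355; adjusted p = 0.980 with an estimated correlation).

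The rising names of this comparison were modest in level. piR-mmu-40529 at 7:73817222–73817248 in an exon of the noncoding gene Gm21269 went from 4.89 ± 0.365 to 23.1 ± 0.321 RPM (SD, n = 2; log2 fold change 2.04 ± 0.47 SE, limma adjusted p = 0.00255, or 0.0566 without negative-control shRNA A). piR-mmu-424500 at 9:54224002–54224032, inside the aromatase gene Cyp19a1, went from 3.79 ± 0.608 to 20.3 ± 2.77 RPM (SD, n = 2; 2.15). The largest rise was that of piR-mmu-48911029 (13:76033503–76033533, 2.45). piR-mmu-192405 (2:69355538–69355567), piR-mmu-26003 (15:78664573–78664603), piR-mmu-51220004 (5:149803556–149803583, Gm21221) and piR-mmu-124194 (5:113351405–113351435) rose by 2.02, 2.02, 1.96 and 1.95. Of the 37 rising names 32 were 29 to 33 nt long, 31 had a single listed locus and 12 lay in the 7 regions that stood out under MC-LR. In those regions 72 names were listed and 56 fell. The chromosome 17 region had 27 lower names of 29, its sum going from 322 ± 92.9 to 27.0 ± 17.1 RPM, and that of chromosome 9 had 12 lower and 3 higher of 16, from 148 ± 45.4 to 35.5 ± 4.28 RPM (SD, n = 2 each). The sum of 18:67039743–67073689 was higher instead, 6.28 ± 1.89 against 16.3 ± 0.982 RPM (SD, n = 2), with 3 of 4 names rising.

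**Figure D3:**
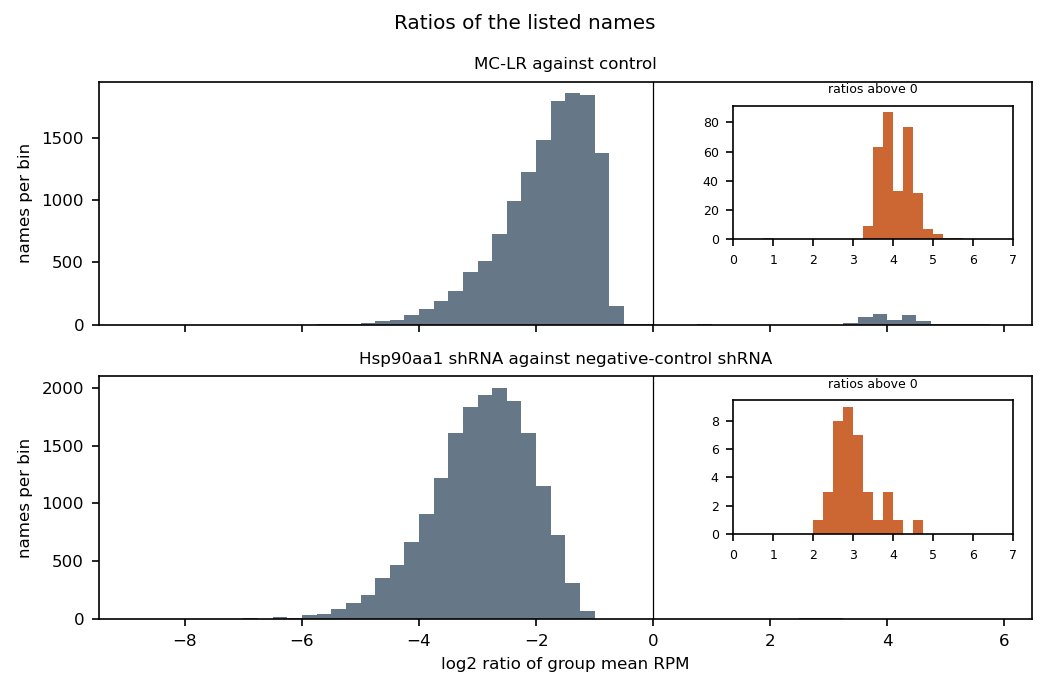
Number of listed names (vertical axis) by log2 ratio of group mean RPM in bins of the ratio (horizontal axis), for MC-LR against control (top) and the Hsp90aa1 shRNA against the negative-control shRNA (bottom), with ratios above 0 enlarged in the insets. Hardly any name lay near 0, with 2 names within 0.5 of it in the MC-LR table and none in the shRNA table; the 99th percentile of lower names was −0.75 and −1.37 and the 1st percentile of higher names 3.41 and 2.30, and scaling within the list moves each whole distribution to a median near 0.

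In the shRNA table all 17375 names were above 0 in each library and 0 names lay within 0.5 of a log2 ratio of 0, and 16858 names had groups that did not overlap, against a share of 0.33 by chance. Scaling within the list (edgeR with TMM factors) moved the median log2 fold change from −2.82, in edgeR on library totals, to −0.02 and left 15 lower and 37 higher names. The class medians of ribosomal RNA (−0.23), transfer RNA (−0.40) and snoRNA (−0.44) stayed below 0 and the other 6 turned above 0. Mirlet7g, the glycine tRNA name piR-mmu-10849969 and the Nlrp4a name piR-mmu-12633674 reversed to 0.85, 0.78 and 0.76.

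Of 10340 names tested in both comparisons, 8119 were lower in both, against 8117.5 for independent lists with these numbers of calls. With the shRNA 10333 of the 10340 were lower, so the overlap was nearly fixed in advance and shows neither sharing nor independence. These calls rest on scaling by library total, since TMM factors leave 320 and 15 lower names. In all, 1 name was higher in both, piR-mmu-63450141 at 18:67043815–67043842, in the chromosome 18 region (log2 fold change 2.46 under MC-LR and 1.98 with the shRNA, limma adjusted p = 4.19e-04 and 0.00115). It was singled out after its values were seen. Of the 314 names higher under MC-LR only 1 was also listed in the shRNA comparison, and of the 37 higher with the shRNA only 1 was listed under MC-LR. The other rising names could therefore not be compared. The sizes of the changes correlated weakly across names, which are not independent replicates (Pearson r = 0.280, Spearman rho = 0.292), and more so for names on long noncoding exons (r = 0.575 over 81 names) and protein-coding exons (r = 0.510 over 526) than on snoRNA (r = 0.143 over 1683) or other small structural RNA (r = −0.0432 over 60); these differences between classes were not tested. Without control A the overall r was 0.157.

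In a test of the difference between both effects, chosen after the data were seen and made across tables that were scaled apart, 178 of 10600 shared names passed in limma, 158 of which fell further with the shRNA and 20 further under MC-LR. These calls depend on the setting: edgeR gave 10 names with TMM factors and 368 on library totals, and limma 281 with a pseudocount of 0.1. The count was 0 without MC-LR A (limma, 1514 names at an unadjusted p under 0.05), 10 without MC-LR B, 69 without control B, 42 and 27 without negative-control shRNA A and B, 37 without Hsp90aa1 shRNA B, 508 without Hsp90aa1 shRNA A and 570 without control A.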

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

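Tests chosen after the data were seen were the scalings and count tools on recovered reads for the calls and named results, the other features given below, the crossed pairing, the test of the difference under every setting and the pseudocount of 0.1 for the correlation between the comparisons; the rest was planned, with edgeR on library totals for that correlation. The calls of higher names kept their counts: 314 to 316 under MC-LR and 36 or 37 with the shRNA in every setting that kept the same names, and all 314 and at least 36 of the 37 were the same names. That stability was fixed by the lists. Their higher names begin far from 0, with a 1st percentile at a log2 ratio of 3.41 under MC-LR and 2.30 with the shRNA. Hardly any name lay between 0 and there to be gained or lost, so the kept counts do not show robust rises. The calls of lower names rest on scaling by the library total. With TMM, RLE and upper quartile factors in edgeR and with DESeq2, MC-LR had 320, 362, 393 and 398 lower names (636, 678, 709 and 714 in all) and the shRNA 15, 15, 16 and 122 (52, 52, 53 and 159 in all). These factors centre each list, so by construction they remove a shift of the whole list and lift the names that were higher. TMM also reversed piR-mmu-10879204 (1.16), piR-mmu-48707800 (0.90), piR-mmu-48788131 (0.12) and piR-mmu-49575097 (0.092) under MC-LR and piR-mmu-10842452 (0.85), piR-mmu-10849969 (0.78) and piR-mmu-12633674 (0.76) with the shRNA; of the 105 named results 56 kept their call and 42 lost it in the same direction. With other features, the counts followed the number tested: names at 1 locus gave 5792 lower of 6079 calls under MC-LR and 9558 of 9589 with the shRNA, names off structural RNA and microRNA genes 3147 of 3459 and 7231 of 7267, and every locus as a feature 15722 of 16073 and 28848 of 28891. Leaving out 1 library gave 5573 to 11101 calls under MC-LR, 5259 to 10787 of them lower; the low ends were without MC-LR A (5259) and MC-LR B (5373), where the lone sample is assumed to vary like the other group, and a cause beyond the smaller sample was not tested. With the shRNA every such count stayed within 1.5-fold. Pseudocount, filters, the FDR of 0.1, the minimum fold and edgeR on library totals kept the counts of both comparisons within 1.5-fold. Of 22 class and length groups, 12 lost their camera call with an estimated correlation and 10 without one passed fry, which tests direction and not difference from other names. The letters share only a name. Their deviations did not go together (r = 0.0652 under MC-LR, −0.608 with the shRNA), and the replicate block gave 9554 lower names under MC-LR and 16252 with the shRNA. The block reversed the camera direction of protein-coding exons under MC-LR, whose median difference is −0.00789, ended the calls of 24 to 28 nt names in both comparisons (adjusted p = 0.106 and 0.0620 by camera on limma values) and lost 3 named results; the cause was not tested. With the letters of the shRNA table crossed, 16822 names were lower and 37 higher. The added test of the difference gave 368 names with edgeR on library totals, 10 with TMM, 281 with a pseudocount of 0.1 and 0 with a replicate block (limma, 1793 at an unadjusted p under 0.05), and 0 to 570 with 1 library left out; the cause was not tested. The correlation between the comparisons ranged from 0.157 without control A to 0.340 without control B. A fit of all 8 libraries with 1 spread was planned for raw counts and not run. By depth the floor is highest in control B, where 3 reads are 0.605 RPM. The median listed name has the fewest reads in the Hsp90aa1 shRNA libraries, 10 and 5, where the sums over names come to 4.98% and 3.18% of the library total.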

Other observations

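Tests in this part were chosen after the results were seen, except those of the opposed replicate letters. Within the 7 extended regions that were higher under MC-LR, the listed names differed in length between the tables. Under MC-LR 51 of 51 names of 24 to 28 nt and 78 of 78 of 29 to 33 nt rose, and the longer ones went from 68.8 ± 28.1 to 905 ± 100 RPM (SD, n = 2). Of 4 names under 24 nt, 1 rose and 1 fell. The regions were picked for rises in this same list, so these shares were largely fixed by the choice and are no measure for the shRNA list. The shRNA table listed mostly names under 24 nt in the same regions, and 48 of 50 of them fell, from 472 ± 162 to 40.6 ± 30.7 RPM (SD, n = 2). Its 11 names of 29 to 33 nt went the other way there, with 10 higher and 1 lower, from 10.9 ± 2.08 to 38.6 ± 5.12 RPM (SD, n = 2). Of its 11 names of 24 to 28 nt 7 fell and 2 rose, from 55.7 ± 3.82 to 35.0 ± 1.31 RPM (SD, n = 2), unlike those of that length under MC-LR. No test was made of the difference between lengths, and scaling within the list (TMM) left only 15 lower names in the whole shRNA table, so most of these 48 falls lose their call.

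The fall of most listed names is the first pattern weighed. A single factor for each library predicts that the gap between the median snoRNA name and the median of other names stays the same. Under MC-LR that gap moved by −1.05 on the log2 scale, against 0.143 between replicates, which argues against one factor as the whole cause there. The test is not independent, since snoRNA was taken after its fall was seen to be the deepest. With the shRNA the gap moved by −0.11, against 0.197 between replicates, which does not decide. One factor would also lower all class sums alike. With the shRNA, other small structural RNA fell 3.58-fold and snoRNA 11.1-fold, with median log2 ratios of −2.28 and −3.26. Their sums went from 1582 ± 240 to 442 ± 48.7 RPM and from 31049 ± 2291 to 2803 ± 200 RPM (SD, n = 2). These classes were picked after their values were seen, and neither differed from the rest with an estimated correlation (camera adjusted p = 0.804 for both). The contrast therefore does not decide on one factor with the shRNA. A broad fall of unselected names would shift the ratios without leaving an empty stretch between lower and higher names. Under MC-LR 1382 names lay at log2 ratios of −1.0 to −0.75, 153 at −0.75 to −0.5 and 1 at −0.5 to −0.25. The 99th percentile of lower names was −0.75 and the 1st percentile of higher names 3.41, against −1.37 and 2.30 with the shRNA. These values argue against a broad fall of unselected names as the whole cause. How much of the fall is selection cannot be told. The share of names within 0.5 of a log2 ratio of 0 was 0.0149% under MC-LR and 0% with the shRNA, against 47.2% and 50.03% for A against B within the reference groups, but this restates the absence of unmoved names and does not test its cause. What the reads outside the lists hold is not known here, and effects of MC-LR and of the shRNA on sperm small RNA stay open as untested.

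The second pattern is the rise of the extended regions under MC-LR. A share of reads freed by the fall of other listed names allows folds near 1.43, the largest ratio of unlisted shares by sums over names that may share reads. The smallest fold among the regions was 10.3, which argues against it as the whole cause of rises of this size. Higher names of the list begin near a log2 ratio of 3.41 (1st percentile), so any region picked for its rises would exceed that bound. A shift of the libraries towards longer inserts predicts that other long names rise and that shorter names of the regions rise less. Of the names of 29 to 33 nt outside the regions 123 of 4560 (2.70%) rose and 3271 fell. A selection on the size of the change would set the share that rose, but it does not turn a rise into a fall. Within the regions, names of 24 to 28 nt went from 18.6 ± 1.98 to 325 ± 58.1 RPM (SD, n = 2). Those of 29 to 33 nt went from 68.8 ± 28.1 to 905 ± 100 RPM (SD, n = 2). So not every listed long name rose, and shorter names of the regions rose too. In the whole MC-LR list, 9 of 2501 names of other lengths were higher by mean RPM. The counts were 105 of 6311 at 24 to 28 nt and 201 of 4638 at 29 to 33 nt, which goes with such a shift. The list left out nearly all unmoved names and the regions were picked for their rises, so these values cannot decide on longer inserts. It cannot be told apart whether only names that rose were listed in these regions, since just 3 of the 133 listed names did not rise and the unlisted ones have no values here. A change in the germ cell origin of these piRNAs under MC-LR may be behind the rise and was not tested.

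The third pattern is that the replicate letters of the shRNA table were opposed. Across names, A minus B in the negative-control group correlated with A minus B in the Hsp90aa1 shRNA group at −0.604. Taking out the median of each RNA class left −0.576, which argues against class composition as the cause. Taking out the median of each insert length left −0.278, short of both bounds set beforehand, so a length profile may carry part of it and cannot be told apart from other causes with 2 libraries a group. No biological explanation was tested.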
